A study of Aspergillus fumigatus with 12 samples.

How the data were processed

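Messenger RNA of mycelium was sequenced from 12 libraries in 4 groups of 3. CK is basic medium, P2R is basic medium with the azo dye Ponceau 2R, SA is basic medium with sinapic acid, and P2R+SA is basic medium with both. Groups and replicate numbers come from the sample titles. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical in part.

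The deposited FPKM values (fragments scaled to gene length and library size) were made by the authors before deposit. The submitters' processing notes name fastp, HISAT2, HTSeq and R 3.2.0, with no role or order for each. The genome build, annotation, strand setting and filters are not given in the sources used here. RNA was taken up in TRIzol and libraries were made with a VAHTS Universal V10 kit, per the labels' protocols. A series-wide table and 12 per-library files hold the same values for 10276 genes, to within 4.9e-06 FPKM. The tests used the series-wide table, whose column names are the sample titles.

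A pair of records disagrees and bears on every comparison. The series design text gives 48 h for all 4 groups, while the column headers of the per-library files hold the number 36 for CK and P2R and the number 48 for SA and P2R+SA. The P2R+SA headers (P2R4SA48) also hold a separate 4 before SA, which no other group has and no source explains. That 4 enters every comparison with P2R+SA, and what it marks was not tested. No source used here says what the header number, 36 or 48, is. If it is a sampling time in hours, every comparison of cultures with and without sinapic acid is also a comparison of 48 h with 36 h, whereas P2R vs CK and P2R+SA vs SA stay within 1 number. P2R vs CK lies at 36 and P2R+SA vs SA at 48, so setting these dye effects against each other also sets 36 against 48. The labels also give the organism as Aspergillus fumigatus, while the series title names Trametes hirsuta.

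The files do not pair gene IDs with names or products. Of the 10276 IDs, 0 matched any identifier of the 10086 genes in an Aspergillus fumigatus Af293 table (assembly ASM265v1), so no gene name, function or coordinate is given. The 23 gene lists that had been fixed by product wording (laccases, peroxidases, cytochrome P450 and others) could not be applied, and 0 of them were run. Reads shared between near-identical copies or overlapping genes could not be checked either.

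Depth was recovered from the values. In the per-library files the FPKM values of a gene stand in ratios of whole numbers between libraries once 1 depth factor per library is divided out. Whole fragments came out for 10273 of 10276 genes (99.97%, within a tolerance of 1e-06), and simulated tables gave identical counts for 99.39% of 10273 genes. The libraries held 35158850 to 38502217 fragments in these genes. Gene lengths came out as whole numbers, within 0.01 bp, for 100.0% of the 9309 genes with over 50 fragments. All of these lengths were multiples of 3, so they are coding lengths, with a median of 1377 bp. Library size therefore differed by little between groups. Because the deposited unit is FPKM, the recovered fragments did not enter the main test. They served for depth, coding length, an alternative test, the comparison of replicates and the simulated data.

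Genes with at least 1 FPKM in 3 or more libraries were tested (9240 of 10276). limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) over all 12 libraries with 8 residual degrees of freedom, an intensity trend and no block. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each of 6 comparisons. The 5 pairs of groups compared were P2R+SA vs P2R, P2R vs CK, SA vs CK, P2R+SA vs CK and P2R+SA vs SA. The sixth, the interaction, is P2R+SA minus P2R less SA minus CK. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. On simulated fragments for 9237 genes with 200 genes changed in P2R+SA vs P2R, the test recovered 23.9% of changes of 0.5 log2 units, 74.6% of changes of 1 and 93.9% of changes of 2. It also called 6 unchanged genes among 134 calls.

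The rule for IDs, fixed before the data were examined together with the tests and most alternatives, takes the 2 largest rises and the 2 largest falls in P2R+SA vs P2R. They must have an adjusted p under 0.05, groups that do not overlap and a mean of at least 5 FPKM in 1 of the groups. Correlations of fold changes are across genes, which are not independent replicates, so they carry no p. For the comparisons that share the CK libraries, 20 simulated sets of unchanged groups with each group's own spread gave the values that shared controls alone produce. A simulation with the spread pooled over groups was run before it and gave higher values; it was replaced because CK libraries spread less than the pooled value.

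Whether the replicate numbers pair the libraries was checked from deviations from group means. Of 18 same-numbered pairs, 3 correlated above 0.1, and values ran from -0.32 to 0.54, so the numbers do not pair the libraries. Replicates of 1 group were never duplicates: a chi-square of recovered fragments over genes was 25.1 to 262 times its degrees of freedom. Alternatives were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, median-of-ratios scaling, quantile normalization, no intensity trend, array quality weights, fits of the compared groups alone, a fold threshold, a replicate block and leaving out each library. Added after seeing the data were limma-voom on the recovered fragments, leaving out the libraries SA replicate 1 and P2R+SA replicate 1 together, and splitting the CK libraries between P2R vs CK and SA vs CK.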

Results

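The series title names Trametes hirsuta, a white-rot fungus that secretes oxidative enzymes able to break down lignin and many dyes, while the samples' organism field gives Aspergillus fumigatus, a mould. Which of them the gene IDs belong to was not settled here. Ponceau 2R is a red azo dye, and sinapic acid is a plant phenolic acid related to lignin building blocks. The series asks how sinapic acid changes gene expression in cultures given the dye. RNA was sequenced from mycelium of 4 groups of 3 libraries: basic medium (CK), the dye (P2R), sinapic acid (SA) and both (P2R+SA). Between 35158850 and 38502217 fragments per library were recovered from the values, and 9240 of 10276 genes were tested. Genes are given by the IDs of the deposited tables, which carry no names, functions or positions.

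CK and P2R libraries each lay together on the first pair of principal components of log2(FPKM + 1), while P2R+SA replicate 1 lay nearer to the SA libraries than to its own group. These components held 44.0% and 27.2% of the variance. Replicates were closest in CK, with Spearman correlations of 0.9946 to 0.9956 between its 3 libraries, and in P2R, with 0.9905 to 0.9953. In SA they were 0.9657 to 0.9773. In P2R+SA, replicates 2 and 3 correlated at 0.9947, while replicate 1 stood apart and the lowest value was 0.9754. The median gene had an SD between replicates of 0.10 log2 units in CK, 0.14 in P2R, 0.22 in SA and 0.21 in P2R+SA (n = 3 each). The headers of the P2R+SA libraries alone also hold a separate 4 of unexplained meaning. The header number of the libraries was 36 in CK and P2R and 48 in SA and P2R+SA, although the series design gives 48 h for all groups. If that number is a sampling time in hours, the effect of sinapic acid and that of time cannot be separated in P2R+SA vs P2R, SA vs CK and P2R+SA vs CK.

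**Figure D1:**
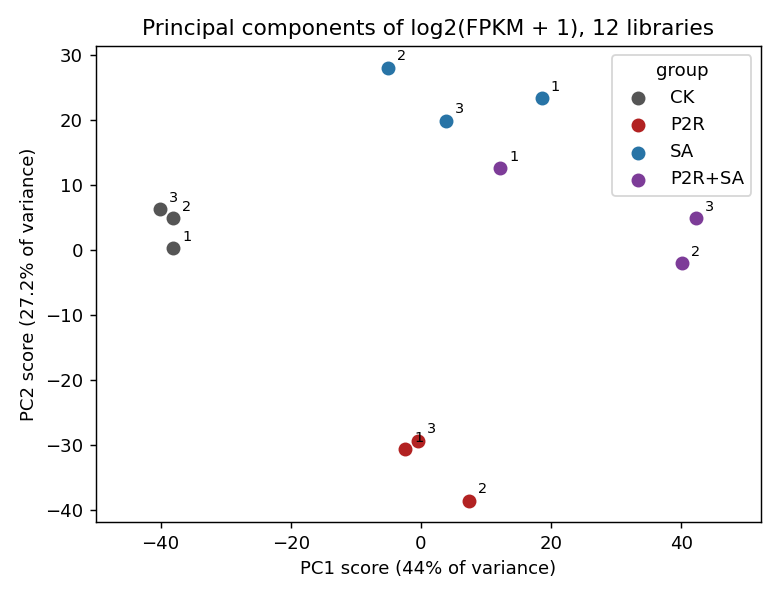
Each point is 1 library, placed by its scores on the first (44.0% of variance) and the second (27.2%) principal component of log2(FPKM + 1) over the tested genes; numbers are replicates. The CK libraries lie at scores of -40.0 to -38.1 on the first axis, P2R+SA replicates 2 and 3 at 40.1 and 42.2, and P2R+SA replicate 1 at 12.2.

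Adding sinapic acid to cultures that held the dye (P2R+SA vs P2R) changed 1828 of 9240 genes (19.8%), 787 higher and 1041 lower. Among the 570 that changed by at least 1 log2 unit, 376 fell and 194 rose. Changes ran from -3.92 to 3.55 log2 units, and the median size among changed genes was 0.75. By the naming rule, the largest rises were in A07391 and A01693. A07391, with a coding length of 675 bp, went from 19.6 ± 6.19 FPKM in P2R to 257 ± 119 FPKM in P2R+SA (SD, n = 3), a 13.1-fold difference of means. Its log2 fold change was 3.55 (SE 0.45, limma adjusted p = 0.000373). A01693, of 1518 bp, went from 1.31 ± 0.37 to 21.5 ± 6.88 FPKM (SD, n = 3), with a log2 fold change of 3.24 (SE 0.29, limma adjusted p = 6.9e-05).

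By the same rule, the largest falls in P2R+SA vs P2R were in A08607 and A01664. A08607, of 1059 bp, dropped from 101 ± 14.8 to 5.78 ± 1.53 FPKM (SD, n = 3), 17.4-fold lower, with a log2 fold change of -3.92 (SE 0.29, limma adjusted p = 2.59e-05). A01664, of 1638 bp, dropped from 67.5 ± 5.97 to 3.94 ± 0.77 FPKM (SD, n = 3), 17.1-fold lower, with a log2 fold change of -3.80 (SE 0.41, limma adjusted p = 0.000161). The majority of falls among all changed genes depended on the scaling: 43.1% of changed genes were higher as deposited, 47.7% after median-of-ratios scaling and 54.1% after quantile normalization. Among changes of at least 1 log2 unit, falls stayed the more frequent, with 356 against 206 and 329 against 212. The count fell to 1089 without P2R replicate 1, 1172 without P2R+SA replicate 3 and 1215 without P2R replicate 3, and was 2943 with SA replicate 1 and P2R+SA replicate 1 both left out and 4700 with array quality weights. All P2R libraries carry the header number 36 and all P2R+SA libraries 48, so a time difference, if that is what it marks, is part of this comparison.

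**Figure D2:**
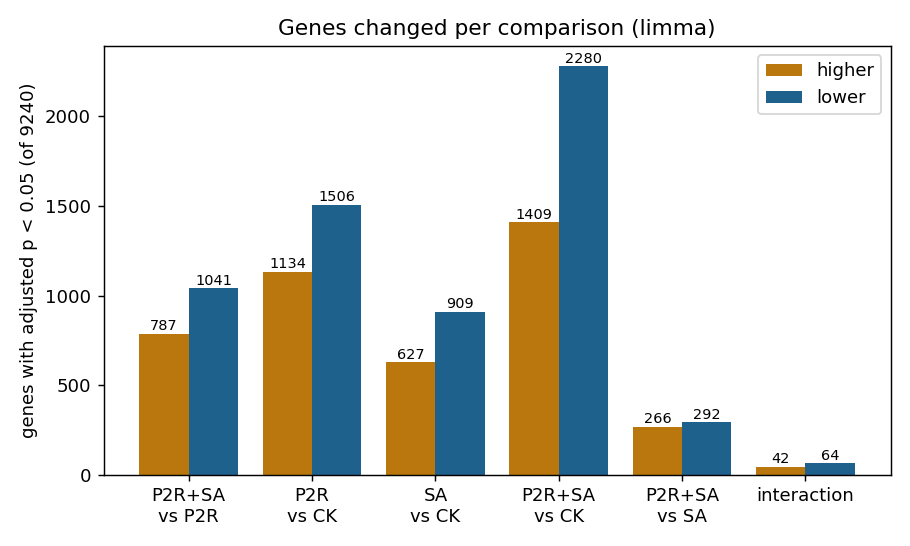
Bars give the number of genes with a limma adjusted p under 0.05, higher (orange) and lower (blue) in the group named first, for each comparison; the interaction is higher where the effect of sinapic acid was more positive with the dye. P2R+SA vs CK holds the tallest pair of bars, with 1409 and 2280 genes, and the interaction the shortest, with 42 and 64.

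The dye alone (P2R vs CK) changed 2640 genes (28.6%), 1134 higher and 1506 lower. On the log2(FPKM + 1) scale, large changes were mostly rises: 422 genes rose and 238 fell by at least 1 log2 unit. That scale compresses changes of low genes. Among genes with a mean under 10 FPKM, 239 were higher and 538 lower, so falls there may have missed the limit. A07391 rose from 4.02 ± 0.05 to 19.6 ± 6.19 FPKM (SD, n = 3; log2 fold change 1.99, SE 0.45, limma adjusted p = 0.00871). A08607, which fell when sinapic acid was added to the dye, rose here from 48.2 ± 2.05 to 101 ± 14.8 FPKM (SD, n = 3; log2 fold change 1.04, SE 0.29, limma adjusted p = 0.0214). That call was lost without any 1 of the CK libraries or without P2R replicate 1 or 2, with limma adjusted p up to 0.0831. A01664 did not pass in the test over all groups (log2 fold change -1.10, SE 0.41, limma adjusted p = 0.0618), nor did A01693 (0.40, SE 0.29, limma adjusted p = 0.324). A01664 passed with the 6 compared libraries alone (limma adjusted p = 0.000113), with limma-voom (0.0318), and in the fit over all groups without SA replicate 1 (0.00044) or 3 (0.0363), within a range of 0.00044 to 0.151 over left-out libraries. With array quality weights, and with SA replicate 1 and P2R+SA replicate 1 both left out, A01664 (limma adjusted p = 0.000451 and 0.000139) and A01693 (0.011 and 0.0408) passed.

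Over all changed genes in P2R vs CK, 43.0% were higher as deposited, 54.2% after median-of-ratios scaling and 45.5% after quantile normalization. The excess of large rises held under both scalings (486 against 192 and 441 against 207). Both kept the pseudocount of 1, so they do not address the compression of low genes. With the compared libraries alone the count was 4531; CK and P2R had the lowest spread between replicates. It was 5137 with array quality weights, 1387 without P2R replicate 2, and 1673, 1477 and 1438 without CK replicates 1, 2 and 3.

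Sinapic acid alone (SA vs CK) changed 1536 genes (16.6%), 627 higher and 909 lower, with 197 rises and 316 falls of at least 1 log2 unit. The share higher was 40.8% as deposited, 47.3% after median-of-ratios scaling and 47.7% after quantile normalization. The strongest fall in this comparison was -4.73 log2 units and the strongest rise 3.22. A07391 rose from 4.02 ± 0.05 to 41.2 ± 27.2 FPKM (SD, n = 3; log2 fold change 2.88, SE 0.45, limma adjusted p = 0.0014), and A01693 from 0.74 ± 0.05 to 6.61 ± 3.40 FPKM (SD, n = 3; log2 fold change 2.04, SE 0.29, limma adjusted p = 0.000803). A01664 dropped from 146 ± 14.9 to 14.8 ± 9.31 FPKM (SD, n = 3; log2 fold change -3.46, SE 0.41, limma adjusted p = 0.000213). A08607 dropped from 48.2 ± 2.05 to 21.8 ± 10.3 FPKM (SD, n = 3; log2 fold change -1.22, SE 0.29, limma adjusted p = 0.0147), and the call was lost without CK replicate 1 (limma adjusted p = 0.0556) or 2 (0.051). With the 6 compared libraries alone its limma adjusted p was 0.05. The count of changed genes was 814, 852 and 894 without CK replicates 1, 2 and 3, and the header number (36 in CK, 48 in SA) changed together with sinapic acid.

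**Figure D3:**
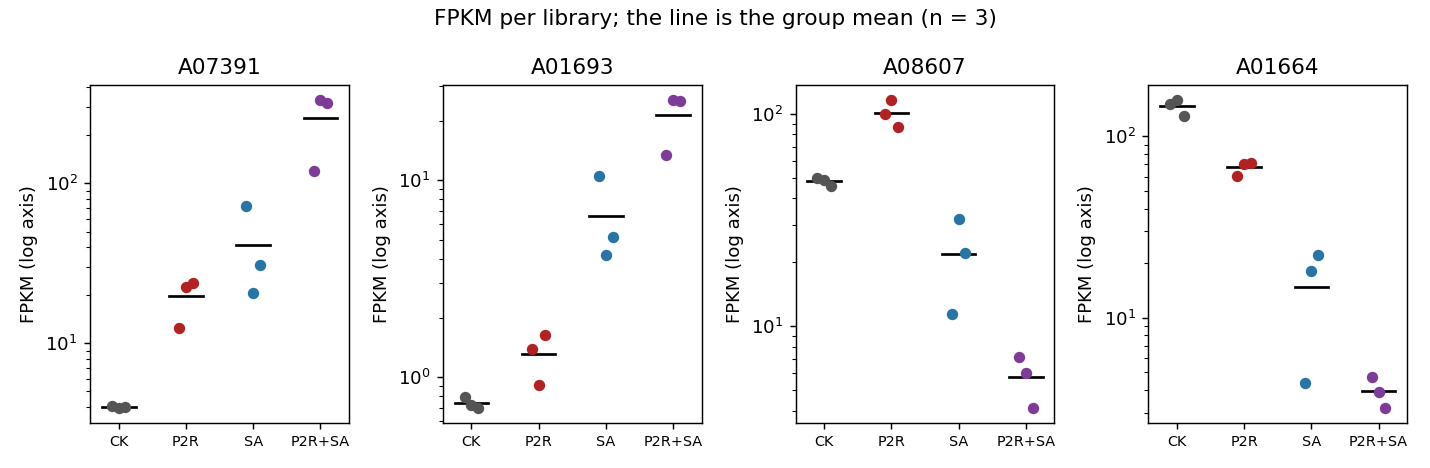
FPKM on a log axis in each of the 12 libraries for the 4 genes with the largest rises (A07391, A01693) and falls (A08607, A01664) in P2R+SA vs P2R; points are libraries and lines are means of 3. A07391 goes from a mean of 4.02 FPKM in CK to 257 FPKM in P2R+SA, and A08607 is highest in P2R at 101 FPKM and lowest in P2R+SA at 5.78 FPKM.

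Both compounds together (P2R+SA vs CK) changed the most genes in the test over all 12 libraries, 3689 (39.9%), with 1409 higher and 2280 lower. A07391 had a mean 63.8-fold higher (log2 fold change 5.54, SE 0.45, limma adjusted p = 7.98e-06), the largest rise of this comparison. A01693 was 29.1-fold higher (3.64, SE 0.29, limma adjusted p = 7.75e-06), A01664 37.1-fold lower (-4.90, SE 0.41, limma adjusted p = 8.39e-06) and A08607 8.34-fold lower (-2.88, SE 0.29, limma adjusted p = 3.37e-05). As deposited, the median of all tested genes lay at -0.11 log2 units in this comparison, against -0.005 after median-of-ratios scaling and -0.01 after quantile normalization. The share of changed genes that were higher was 38.2% as deposited, 50.8% after median-of-ratios scaling (1863 higher, 1803 lower) and 49.2% after quantile normalization (1861 higher, 1924 lower). The count was 2415 and 2389 without P2R+SA replicates 2 and 3 and 6656 with array quality weights, and the header number differed here too (36 in CK, 48 in P2R+SA). P2R vs CK had more genes without P2R+SA replicates 2 and 3 (2450 and 2570). It also had more with the compared libraries alone (4531, against 3708 in P2R+SA vs CK).

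Adding the dye to cultures that held sinapic acid (P2R+SA vs SA) changed 558 genes (6.0%), 266 higher and 292 lower as deposited, 347 and 273 after median-of-ratios scaling, and 339 and 270 after quantile normalization. A07391 rose from 41.2 ± 27.2 to 257 ± 119 FPKM (SD, n = 3; log2 fold change 2.66, SE 0.45, limma adjusted p = 0.00688) and A01693 from 6.61 ± 3.40 to 21.5 ± 6.88 FPKM (SD, n = 3; log2 fold change 1.60, SE 0.29, limma adjusted p = 0.00981). A08607 dropped from 21.8 ± 10.3 to 5.78 ± 1.53 FPKM (SD, n = 3; log2 fold change -1.67, SE 0.29, limma adjusted p = 0.00797), and A01664 did not pass (-1.44, SE 0.41, limma adjusted p = 0.0585). These calls lean on the spread borrowed from CK and P2R. With the 6 compared libraries alone, 32 genes changed, and A07391, A01693 and A08607 no longer passed (limma adjusted p = 0.0847, 0.12 and 0.113). The count was 1888 without P2R+SA replicate 1, 881 without SA replicate 1, 148 and 228 without P2R+SA replicates 2 and 3, and 330 to 362 without any 1 CK library or without P2R replicate 1 or 3. It was 2249 with SA replicate 1 and P2R+SA replicate 1 both left out and 2020 with array quality weights. A01693 also lost its call without P2R+SA replicate 2 (limma adjusted p = 0.0601), and A01664 passed without SA replicate 1 (7.64e-05), P2R+SA replicate 1 (0.0422) or both (1.74e-05), and with array quality weights (0.00519).

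The effects of sinapic acid (with the difference in header number in both) without the dye (SA vs CK) and with it (P2R+SA vs P2R), which share no library, went mostly the same way. Across the 9240 genes the fold changes correlated at a Pearson r of 0.63 and a Spearman rho of 0.52. Of 813 genes changed in both, 294 were higher in both and 497 lower in both, where independent lists would share 53.4 and 102.4. In the opposite directions, 18 genes were higher without the dye and lower with it, and 4 the reverse, against 70.6 and 77.4 for independent lists. Each gene's spread was estimated over the same 12 libraries for both comparisons, which favours shared calls, so independent lists are no chance level. After the sampling error was taken out, the SD of the fold changes was 0.50 log2 units in each of these comparisons.

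The effects of the dye without sinapic acid (P2R vs CK) and with it (P2R+SA vs SA), also without shared libraries, correlated at a Pearson r of 0.61 and a Spearman rho of 0.57. Of 359 genes changed in both, 174 were higher in both and 179 lower in both, against 32.6 and 47.6 for independent lists. Here too the estimate of each gene's spread was shared, so independent lists are no chance level. The SD of the dye's fold changes after the sampling error was taken out was 0.57 log2 units without sinapic acid and 0.33 with it, and leaving out 1 library gave 0.54 to 0.58 and 0.22 to 0.44. This difference in overall size was not tested beyond those ranges. P2R vs CK lies at header number 36 and P2R+SA vs SA at 48. If that number is a sampling time, sinapic acid and time cannot be told apart in this difference either.

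**Figure D4:**
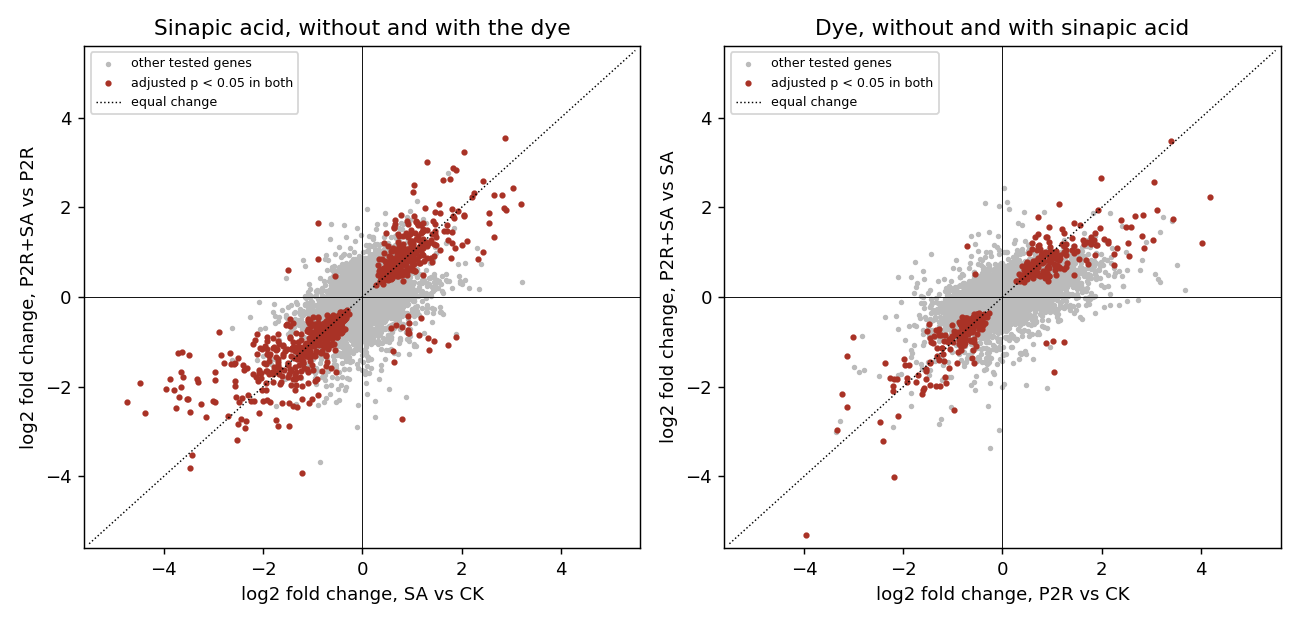
Each point is 1 of the 9240 tested genes. The left panel plots the log2 fold change for sinapic acid with the dye (P2R+SA vs P2R) against that without it (SA vs CK), and the right panel the log2 fold change for the dye with sinapic acid (P2R+SA vs SA) against that without it (P2R vs CK). Red points passed in both comparisons (813 genes on the left, 359 on the right), and the dotted line marks equal change. The noise-corrected SDs were 0.50 log2 units on both axes of the left panel, and 0.57 (horizontal) and 0.33 (vertical) in the right panel. In the right panel the horizontal axis compares libraries of header number 36 and the vertical axis libraries of 48.

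The dye alone and sinapic acid alone were compared with the same CK libraries. Their fold changes correlated at a Pearson r of 0.45 and a Spearman rho of 0.44, where unchanged groups against shared controls gave 0.25 and 0.26 in simulation. The covariance was 0.1443 against 0.0082 in simulation, an excess of 0.1361. Of 644 genes changed by both, 241 were higher in both and 317 lower in both, against 77.0 and 148.2 for independent lists and 0.05 each in simulation. The simulated groups were unchanged, so few genes could be called there. The 0.05 therefore cannot show how much overlap shared controls add to lists of this size. With the CK libraries split between the comparisons, 1 for one and 2 for the other, the 6 splits gave a Pearson r of 0.35 to 0.48, a Spearman rho of 0.32 to 0.46 and a covariance of 0.1197 to 0.1501. The overlap of calls was not recounted with split controls. Part of it may come from the shared CK libraries or from the shared estimate of each gene's spread.

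The interaction asks whether the effect of sinapic acid differed with and without the dye. It passed for 106 genes (1.1%), with 1350 at an unadjusted p under 0.05. In 64 of them the effect of sinapic acid was more negative with the dye. Of these, 55 were higher in P2R than in CK, 35 were higher in SA than in CK, and 47 were lower in P2R+SA than in P2R. Their median log2 differences from CK were 1.3 in P2R, 0.60 in SA and 0.49 in P2R+SA. In the other 42 genes, 31 were lower in P2R than in CK and 31 lower in SA than in CK, with medians of -0.91 in P2R, -1.20 in SA and -0.92 in P2R+SA. Between P2R+SA and P2R these 42 genes were mixed, with 15 higher, 13 lower and a median log2 difference of -0.02. The log2(FPKM + 1) scale compresses changes of low genes. A mean under 10 FPKM was found in 19 of the 42 and 13 of the 64, against 3026 of 9240 tested genes. With a pseudocount of 0.1, 29 genes passed with a higher and 54 with a lower interaction, and with limma-voom 29 and 52. Whether a floor in low genes makes part of the 42 was not tested. A08607 was among the 64, with a log2 interaction of -2.71 (SE 0.41, limma adjusted p = 0.0095). A08607 had been picked as the largest fall in P2R+SA vs P2R, which enters the interaction, and that choice favours a negative value. Its log2 change with sinapic acid was -1.22 without the dye and -3.92 with it. An additive effect of time would cancel in the interaction. A dye effect that differs between header numbers 36 and 48, if they are times, would not cancel. It could not be separated from the interaction, as the number goes with sinapic acid in every library.

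For the interaction, A07391, A01693 and A01664 did not pass (limma adjusted p = 0.658, 0.206 and 0.825). Without SA replicate 1, A01693 and A01664 passed (limma adjusted p = 0.0453 and 0.0429). With SA replicate 1 and P2R+SA replicate 1 both left out, all 3 passed (limma adjusted p = 0.0301, 0.00195 and 0.0136), and the log2 interaction of A07391 went from 0.68 to 1.65. These libraries were picked after seeing the data. Leaving them out also lowered the shared estimate of spread: P2R vs CK, which kept all its libraries, went from 2640 to 3911 genes. Calls gained this way are therefore partly by construction. A01693 also passed with array quality weights (limma adjusted p = 0.0101), and without SA replicate 3 the interaction of A01664 turned from -0.34 to 0.059 (0.978). The interaction shares libraries with the effects inside it, and in simulated unchanged groups it correlated at -0.48 with P2R vs CK and at -0.74 with SA vs CK, against -0.70 and -0.45 observed, so the directions counted inside the 106 genes are not independent of the call. The count was 36 to 50 without any 1 CK or P2R library, 173 without SA replicate 1 and 330 without SA replicate 2. It was 345 with SA replicate 1 and P2R+SA replicate 1 both left out and 494 with array quality weights.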

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

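The tests of the header number, of depth and of how far the response had gone were chosen after the results they concern were seen. So were the overlap of calls after scaling and the share of fold changes that length accounts for. The test of length-dependent loss of RNA names SA replicate 1 and P2R+SA replicate 1, libraries picked after seeing the data. It therefore does not count as set before. The length test on the correlation and the test of calls under scaling were set before.

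The effect of sinapic acid differed with and without the dye for 106 genes, by the interaction term of the limma fit. A08607, picked for its fall in P2R+SA vs P2R, was one of them, with a log2 interaction of -2.705. If the header number is a time, a dye effect that changes with time cannot be told apart from the interaction. Of 100 splits of the libraries within each dye condition, 7 gave at least 106 genes, the real one included, and the highest other gave 2903. The 7 are no chance level, and the splits leave chance open: each of the 6 others exchanged 4 or 6 labels in 1 dye condition and none in the other, which puts the effect common to both conditions into the interaction, while the 80 splits that exchanged labels in both gave 0 genes with that effect in the spread. For the 5 pairs of groups, 10 splits are too few to show a share under 0.05, and 1 split of 10, the real one, gave as many genes in each. The real and highest other counts were 1828 and 4 for P2R+SA vs P2R, 2640 and 0 for P2R vs CK, 1536 and 0 for SA vs CK, 3689 and 0 for P2R+SA vs CK, and 558 and 252 for P2R+SA vs SA.

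The effects of sinapic acid with and without the dye correlated at 0.63. A length bias common to both comparisons is argued against, since a curve on coding length accounted for 0.20% of the variance of the fold changes in SA vs CK and 0.40% in P2R+SA vs P2R; taking it out left the correlation at 0.626. A shift of scale by a few abundant genes is argued against too, not by the correlation, which a factor common to all genes hardly moves, but by the calls: 1758 of the 1828 genes called in P2R+SA vs P2R were called the same way after median-of-ratios scaling, and 377 genes were then higher and 495 lower in both comparisons, against 83.9 and 102.6 for independent lists. Those values are no chance level, since the comparisons share the estimate of each gene's spread. The header number stays open: in 12 of 12 libraries it goes with sinapic acid (48 with it, 36 without), so if it is a sampling time, sinapic acid and time cannot be told apart in SA vs CK, P2R+SA vs P2R or P2R+SA vs CK. Sinapic acid itself, the effect that the design names, is equally open.

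Libraries with sinapic acid spread more than the others, with median SDs of 0.22 and 0.21 log2 units against 0.10 and 0.14. Lower depth is argued against by a ratio of mean fragments of 0.997 between libraries with and without it. Length-dependent loss of RNA is argued against for SA replicate 1 and P2R+SA replicate 1, where coding length accounted for at most 1.73% of the variance of the deviations. The deviation of P2R+SA replicate 1 from replicates 2 and 3 correlated at -0.431 across genes with SA vs CK and at -0.539 with P2R vs CK, neither of which shares a library with it. As a hypothesis, this culture may have gone less far along the response than the others of its group. A batch or an uneven dose would look alike and were not tested. The hypothesis concerns P2R+SA replicate 1 only. In SA, the chi-square between replicates was 213 to 262 times its degrees of freedom in every pair. Between P2R+SA replicates 2 and 3 it was 36.2 times. The wider spread in SA was left without an account.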

How the results depend on the processing

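Leaving out SA replicate 1 and P2R+SA replicate 1 together, limma-voom on recovered fragments, the split of the CK libraries and the counts over all 4 single steps were chosen after seeing the data. Counts of changed genes stayed within 1.5 times under both pseudocounts, all filters, both scalings, no intensity trend and limma-voom. Requiring 1 log2 unit left 570 genes in P2R+SA vs P2R, 660 in P2R vs CK, 513 in SA vs CK, 1026 in P2R+SA vs CK and 208 in P2R+SA vs SA. Array quality weights, which lower the weight of scattered libraries, gave 4700, 5137, 6656 and 2020 in the same order without SA vs CK, and 494 for the interaction. Fits of the compared libraries alone gave 4531 in P2R vs CK and 32 in P2R+SA vs SA, by construction from their own spread. Without SA replicate 1 and P2R+SA replicate 1, the counts were 2943 in P2R+SA vs P2R, 2249 in P2R+SA vs SA and 345 for the interaction. Leaving out 1 library gave 1089 to 2421 in P2R+SA vs P2R, 1387 to 3392 in P2R vs CK, 814 to 2211 in SA vs CK, 2389 to 4740 in P2R+SA vs CK, 148 to 1888 in P2R+SA vs SA and 36 to 330 for the interaction. The 3 correlations of fold changes ran from 0.556 to 0.696, 0.504 to 0.682 and 0.385 to 0.486 when 1 library was left out; the last averaged 0.414 with CK libraries split between its comparisons. With a replicate block, though the numbers do not pair the libraries (2 of 12 correlated best with their own number), 1622, 2380, 1329, 3495, 392 and 65 genes changed; only the interaction moved by over 1.5 times. Of 548 values of the 4 named genes under alternatives, 517 kept direction and side of the threshold, 12 lost the call, 18 gained it and 1 turned: the interaction of A01664 was -0.995 to 0.059 when 1 library was left out. These genes were picked as the largest changes in P2R+SA vs P2R, and several alternatives leave a fold change as it was. The 517 are therefore no measure for other genes. Where no construction is named, the cause was not tested. With 3 libraries per group, the simulated test found 23.9% of changes of 0.5 log2 units in P2R+SA vs P2R. That simulation changed 200 of 9237 genes, whereas 1828 genes were called in the data. The p-value that an adjusted p under 0.05 requires depends on how many genes change, so this share does not carry over to the data. Small changes may have been missed.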

Other observations

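The counts over single steps were chosen after the results were seen; the tests of neighbouring IDs were set before, except that the margin asked of the value at a distance of 3 numbers (over 1 SD of the shuffled values) was set after it was seen. A group of 30 genes rose in all 4 single steps of the design, that is when the dye was added without and with sinapic acid and when sinapic acid was added without and with the dye, and 52 genes fell in all 4. Independent lists of these sizes would give 0.19 and 0.53 genes, but the steps share libraries, so that is not a chance level for this design. A07391 was among the 30. The counts rest on the pooled spread and on P2R+SA replicate 1: they were 79 and 203 without it, and 2 and 2 when each step was tested on its own libraries. Without SA replicate 1 they were 34 and 87, and without any 1 CK or P2R library, SA replicate 3 or P2R+SA replicate 2 or 3 they were 10 to 20 and 18 to 34. Array quality weights gave 156 and 241, and leaving out SA replicate 1 and P2R+SA replicate 1 together gave 110 and 242. The excess of falls depended on the scaling: 53 rose and 42 fell after median-of-ratios scaling, and 40 and 41 after quantile normalization. The 10 genes with the highest mean took 10.8% to 12.5% of the FPKM total in the CK, P2R and SA libraries and 13.1% to 14.3% in P2R+SA.

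Fold changes of genes with adjoining ID numbers correlated at 0.098 in P2R+SA vs P2R, against at most 0.035 in 1000 shuffled orders, and at 0.101 to 0.116 in the other 5 comparisons. At a distance of 2 numbers, P2R+SA vs P2R (0.038, shuffled up to 0.043) and P2R vs CK (0.040) did not exceed the shuffled orders, while the other 4 comparisons did, with 0.043 to 0.048 against at most 0.035 to 0.040. At a distance of 3, P2R+SA vs P2R alone lay above its shuffled range (0.038 against 0.033), by less than the SD of the shuffled values (0.011), and the other 5 gave 0.016 to 0.032. A candidate explanation is that the numbers follow the genome and that gene neighbourhoods respond together, which stays open because no comparison lay above its range at each distance from 1 to 3. Reads counted for a pair of adjoining genes were another candidate. The rule set before asked only whether the value at a distance of 3 exceeded all shuffled orders. In P2R+SA vs P2R it did (0.038 against 0.033), which by that rule argues against such reads there. The margin added after the value was seen is what leaves them open. The other 5 comparisons lay within their shuffled ranges at that distance. Tandem copies were not tested.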
